A study of Mus musculus with 9 samples.

How the data were processed

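Poly(A) RNA was sequenced from isolated glomeruli of 9 male C57BL/6 mice, 5 controls and 4 animals in which a Cre transgene active in podocytes (Podo-Cre) was combined with a floxed Cosmc allele (Cosmc KO). Groups, replicate numbers, ages and genotypes were taken from the sample labels. Each library comes from a separately numbered animal, so p-values measure the spread between animals as the labels name them.

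The submitters' processing notes name STAR 2.5.2b, featureCounts, Subread 1.5.2 and DESeq2 (no version given) with the mouse build GRCm38. Filters, the annotation release and the strandedness of the counting were not given in the sources used here. A single table of 16867 genes was deposited. Its sample columns hold a signal, per the file headers and the values: gene read counts that the authors divided by a single size factor per library. The mean column, also a deposited signal, equals the mean of the 9 sample columns, and its lowest value is 8.73. The authors' deposited columns also give the log2 fold change between the groups with its standard error, a Wald statistic (a score, per the file headers), a p-value and an adjusted p-value. For 1 gene no p-value is listed. No per-sample column was left unused.

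Within each library, 100% of the values were whole multiples of a single step to within 0.01 of the step, so the underlying reads could be recovered. For control 3 the step differs from 1 by less than rounding alone can exclude (its size factor was 0.999), so count-based tests were also run without this library. Reads recovered over the listed genes ranged from 31.5 to 58.1 M per library. Counting intervals are exact binomial intervals at the 95% level and cover counting error only. No 2 libraries agreed within counting noise (lowest chi-square per degree of freedom 26.1 over all pairs), so all 9 were kept as separate samples.

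A count-based test in edgeR had been planned for raw counts. Because the deposited values are scaled, the main test was limma 3.58.1 with a mean-variance trend on log2(value + 1), in R 4.3.3, on the 16764 genes with a value of at least 10 in at least 4 libraries. Benjamini-Hochberg adjusted p-values under 0.05 were called. Fold changes on the log2(value + 1) scale understate the change of genes with low values. All 9 libraries entered the fit with group as the only term. A second comparison, among the controls alone, set the 3 Cre-carrying controls against the 2 without Cre.

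The fixed gene lists (23), the rule for named genes, the tests and most alternatives were set before the data were examined. Named genes were C1galt1c1 and the podocyte genes Nphs1, Podxl, Pdpn, Wt1 and Synpo. Added to these were up to 12 higher and 12 lower genes with the largest log2 fold change among those called, with a mean CPM (reads scaled to a common library size) of at least 1 in a group, no overlap between the groups and a symbol that is not a predicted gene, clone or pseudogene. Each list gave up to 4 called members, or its 2 most abundant members where none was called. Up to 3 genes called between Cre-carrying and Cre-free controls were added. This gave 98 genes, some of which are not reported here. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, with fry, and with a two-sided exact permutation test of its score over all 126 splits of the libraries. The score is the mean log2(value + 1) of the list's members in a library. The smallest p this permutation test allows is 0.00794. Set-test p-values were adjusted over the 23 lists.

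Control and Cosmc KO animals share the numbers 1 to 4 in the labels, and animals with the same number share an age. Deviations from the group means correlated at 0.54, 0.51, 0.34 and 0.27 between same-numbered libraries, and 2 of the 4 Cosmc KO libraries correlated best with their own number. The numbers were taken to pair the samples because every pair was above 0.1. However, libraries with different numbers also passed this cutoff, such as control 2 with Cosmc KO 3 (0.53) and control 5 with Cosmc KO 4 (0.33). The check therefore does not show that the animals are paired. A paired fit with the replicate number as a block (4 pairs, control 5 left out) is given beside results that it changes. The pairing is thus assumed from the labels' numbers and ages, and the labels do not say that paired animals were littermates.

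Alternatives were DESeq2 1.42.0, limma-voom, edgeR 4.0.16 (the quasi-likelihood test with TMM factors) on the recovered reads, other scaling factors, no filter or a filter of 1 CPM in at least 4 libraries, an age factor, Cre-carrying controls only, the proximal tubule score as a covariate, pseudocounts of 0.5 and 4, and leaving out each library. They were run in the limma model unless they name another tool. edgeR, TMM rescaling, the pseudocounts and leaving out Cosmc KO 2 and 3 together, leaving out the Cre-free controls in the comparison of controls, and estimated correlations in the paired, tubule-covariate and other alternative fits were added after the data were seen. On data simulated from these libraries' means for the Cosmc KO comparison (16739 genes tested), limma recovered 73% of changes of 1 on the log2 scale. It recovered 100% of changes of 2 and called 0.0423% of unchanged genes. The simulation drew each gene independently, without variation shared between genes, so this rate of false calls need not hold for the real libraries. DESeq2 on the recovered reads gave log2 fold changes within 0.000199 of the authors' deposited values for all 16867 genes.

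Gene positions came from GENCODE release 21 for GRCm38. Of the 16867 symbols 16389 matched it, 31 of them more than 1 gene. Of the 96 named genes with a single match, 28 share exon sequence with another annotated gene, so their values carry an uncertainty from overlapping or antisense reads. Near-identical copies (such as Hba-a1 with Hba-a2, and Hbb-bs with Hbb-bt) can share reads as well. Figures were drawn with matplotlib 3.10.9.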

Results

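Glomeruli, the filtering units of the kidney, were compared between 5 control mice and 4 mice lacking Cosmc in podocytes, the epithelial cells that wrap the glomerular capillaries. Cosmc, listed under the symbol C1galt1c1, is the X-linked chaperone that the enzyme C1galt1 needs to build core 1 mucin-type O-glycans. All animals were males aged 30 to 35 days. Controls 1, 4 and 5 carried Podo-Cre with an intact Cosmc allele, control 2 carried a floxed Cosmc allele without Cre, and control 3 carried neither. Sequencing gave 41.8, 31.5, 41.4, 38.1 and 37.0 M reads over the listed genes in controls 1 to 5. The totals were 35.0, 47.0, 55.6 and 58.1 M in Cosmc KO 1 to 4. Values are normalized read counts, as mean ± SD with n = 5 controls and n = 4 Cosmc KO. Fold changes are Cosmc KO minus control on the log2(value + 1) scale ± SE from limma, with Benjamini-Hochberg adjusted p.

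The deleted gene was examined first, in every library. C1galt1c1 fell from 1468 ± 69.7 in controls to 961 ± 159 in Cosmc KO (log2 fold change -0.63 ± 0.11, adjusted p = 0.0111). The controls read 1552, 1508, 1487, 1385 and 1409, and the Cosmc KO libraries 1123, 939, 1030 and 751, so the groups did not overlap. The floxed control without Cre, control 2, lay within the range of the other controls. C1galt1c1 lies on the minus strand of chromosome X, from 38630785 to 38635087 in GRCm38, and its coding sequence (38631170 to 38632117) is contained in exon 2. The labels do not say which part is floxed, and the preparation also holds endothelial, mesangial and parietal cells, in which no deletion is stated. C1galt1, the partner enzyme, had a log2 fold change of -0.04 (adjusted p = 0.786). Against the 3 Cre-carrying controls alone, the C1galt1c1 difference was -0.61 with an adjusted p of 0.081, and without Cosmc KO 2 and 3 it was -0.67 with an adjusted p of 0.0711.

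**Figure D1:**
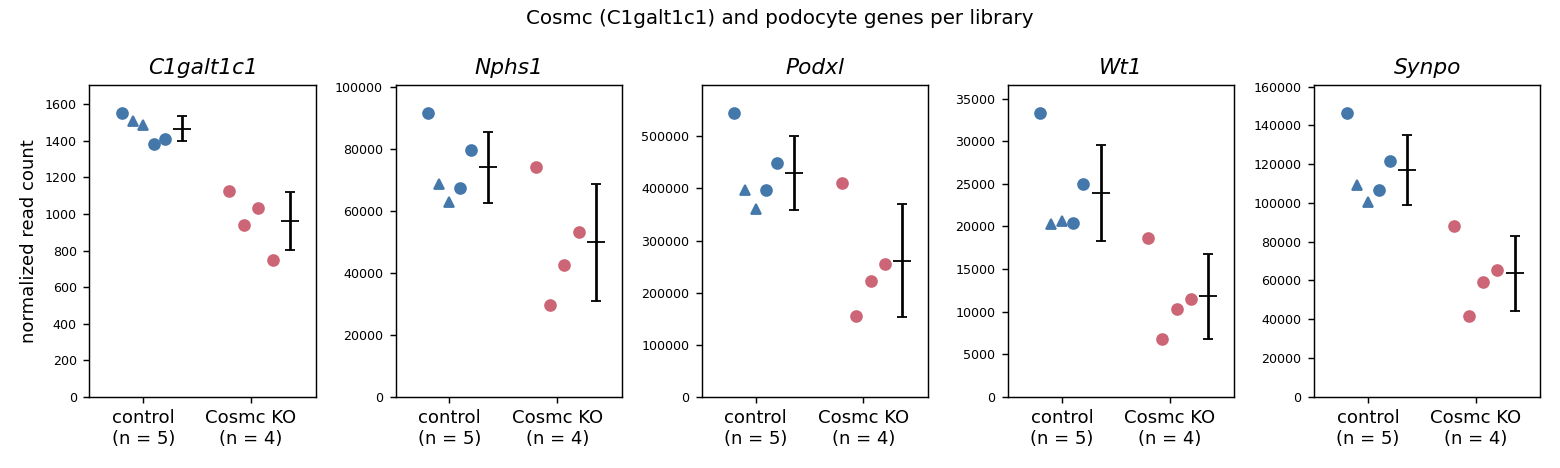
Normalized read counts of C1galt1c1 and 4 podocyte genes in each library, with 5 controls in blue and 4 Cosmc KO in red; circles mark animals with Cre, triangles animals without, and black bars the mean ± SD of each group. C1galt1c1, Wt1 and Synpo separate the groups, whereas Nphs1 and Podxl of Cosmc KO 1 (74220 and 410919) lie within the control range.

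Across the transcriptome, 1298 of 16764 genes differed between the groups, 698 of them higher and 600 lower in Cosmc KO. A total of 4603 genes had an unadjusted p under 0.05. For 2003 genes (11.9%) the 4 Cosmc KO and 5 control libraries did not overlap, against 1.59% by chance. The authors' deposited table calls 1447 genes higher and 1252 lower, among them all 1298 in the same direction. With the replicate number as a block, 2790 genes differed (1601 higher, 1189 lower), including 1219 of the 1298. Cosmc KO 1 stood apart from the other Cosmc KO libraries: 4884 genes were called without it, whereas leaving out any 1 of the other 8 libraries gave between 523 (without Cosmc KO 3) and 828 (without control 3). The Cre-carrying controls alone gave 438 genes, the proximal tubule score as a covariate 730, DESeq2 2699 and the data without Cosmc KO 2 and 3 together 305.

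Among the named genes, the largest log2 fold change on the log2(value + 1) scale was that of Gdf6, a growth factor of the bone morphogenetic protein family (chromosome 4, 9844372 to 9862345), from 1.70 ± 2.11 to 209 ± 179 (log2 fold change 6.24 ± 0.59, adjusted p = 0.000474). Havcr1, which encodes the kidney injury molecule KIM-1, went from 15.4 ± 14.2 to 1102 ± 1084 (5.74 ± 0.82, adjusted p = 0.00347). Spon2, a secreted matrix protein, rose from 76.8 ± 44.8 to 1804 ± 233 (4.70 ± 0.34, adjusted p = 0.000159). Gpr176, a G protein-coupled receptor, rose from 4.40 ± 2.93 to 134 ± 10.2 (4.78 ± 0.34, adjusted p = 0.000159). Mmp10, a secreted metalloproteinase, had 1 read in all controls and 294 in Cosmc KO, a ratio of 285 (95% counting interval 50.8 to 11310). Crct1 likewise had 1 control read against 390, a ratio of 379 (67.6 to 14991). Serpina10, Gpr165, Il1f6 (an interleukin-1 family cytokine), Sprr1a, Krt20 and Fgg (the fibrinogen gamma chain) rose by 5.50, 5.40, 5.06, 5.02, 4.90 and 4.70 on the log2 scale.

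Among the genes that fell most, Mgat5b, a glycosyltransferase of O-mannosyl glycans, fell from 623 ± 293 to 70.2 ± 47.3 (-3.31 ± 0.51, adjusted p = 0.00527). Nectin4, a cell adhesion protein (chromosome 1, 171370099 to 171388598), fell from 1096 ± 212 to 207 ± 33.1 (-2.39 ± 0.16, adjusted p = 0.000145). Lect1, which encodes chondromodulin, fell from 94.1 ± 14.2 to 14.5 ± 1.49 (-2.61 ± 0.19, adjusted p = 0.000159). Cyp26a1, which degrades retinoic acid, fell from 141 ± 106 to 13.3 ± 8.63 (-3.25 ± 0.56, adjusted p = 0.00915). Slc30a10, Lingo2, Cacna2d2, Gdf5, Adamtsl3, Fgfbp1, Astn2 and Pvalb had log2 fold changes of -3.62, -2.67, -2.53, -2.38, -2.32, -2.31, -2.25 and -2.24. Slc30a10 was not called when any 1 of controls 1 and 2 or Cosmc KO 2 and 4 was left out (adjusted p = 0.0504 to 0.0663).

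**Figure D2:**
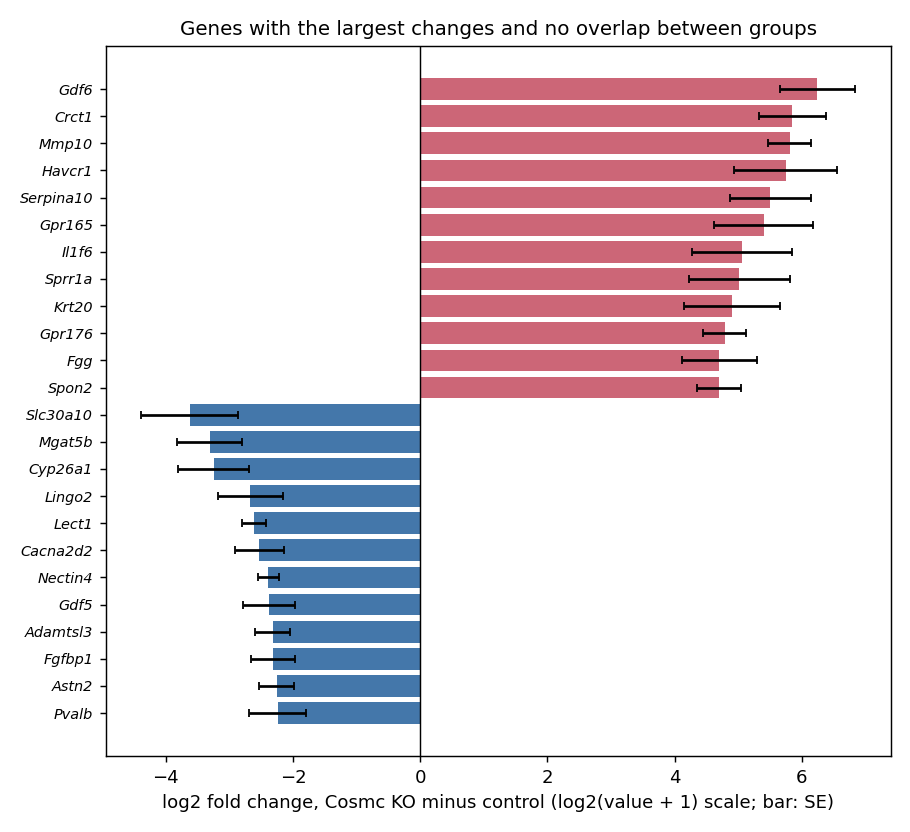
Log2 fold changes (Cosmc KO minus control, log2(value + 1) scale) of the 12 higher and 12 lower named genes with the largest changes; red bars are higher and blue bars lower in Cosmc KO, and black lines are the SE from limma. The changes range from 6.24 for Gdf6 to -3.62 for Slc30a10.

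Podocyte genes were lower in Cosmc KO. Of 43 measured members of the podocyte list, 20 fell, none rose and 23 did not pass, and 31 fell when p was adjusted over the list alone. The median log2 fold change was -0.80. Wt1, the podocyte transcription factor, fell from 23923 ± 5604 to 11800 ± 5004 (-1.09 ± 0.27, adjusted p = 0.0376), and Synpo, which encodes the actin-binding synaptopodin, fell from 116861 ± 18178 to 63642 ± 19319 (-0.92 ± 0.22, adjusted p = 0.035). Shisa3 fell furthest (32363 ± 6888 to 8654 ± 4796, -2.05 ± 0.33, adjusted p = 0.00662), and Sema3g, Plce1 and Rhpn1 had log2 fold changes of -1.44, -1.45 and -1.06. Nphs1 (nephrin), Podxl (podocalyxin) and Pdpn (podoplanin) did not pass, at -0.63, -0.79 and -0.74 (adjusted p = 0.133, 0.139 and 0.0561). The authors' deposited Wald test calls Podxl and Pdpn (adjusted p = 0.0389 and 0.0248) but not Nphs1 (adjusted p = 0.0935). All 3 passed in the paired fit (adjusted p = 0.0362, 0.0338 and 0.00917) and 30 members of the list fell. The podocyte score of Cosmc KO 1 (14.28) lay within the control range of 14.27 to 14.75, and those of Cosmc KO 2 to 4 were 13.10, 13.55 and 13.82. The score differed between groups (difference -0.76, exact permutation p = 0.0159, adjusted p = 0.0456), and camera gave an adjusted p of 1.28e-12 at the preset correlation but adjusted p = 0.484 with an estimated correlation. Without Cosmc KO 1, 32 members fell, while leaving out any 1 of the other 8 libraries left 2 (without Cosmc KO 3) to 13 (without control 3). Wt1 and Synpo were each no longer called when any 1 library other than Cosmc KO 1 was left out (adjusted p = 0.0603 to 0.109 and 0.0555 to 0.106). Without Cosmc KO 1, Nphs1, Podxl and Pdpn passed (adjusted p = 0.0161, 0.0234 and 0.0027). In that fit, however, the proximal tubule scores of Cosmc KO 2 to 4 (11.74 to 12.69) all lay above those of the controls (up to 11.38). Group and tubule content cannot be told apart there. With the tubule score as a covariate and all libraries, Nphs1, Podxl and Pdpn did not pass (adjusted p = 0.553, 0.545 and 0.177). Sema3g and Plce1 were not called without Cosmc KO 3 (adjusted p = 0.058 and 0.0536). With the proximal tubule score as a covariate, 7 members fell and the median was -0.42. Wt1 and Synpo were not called in that fit (-0.64 and -0.60, adjusted p = 0.0921 and 0.122).

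Among 25 slit diaphragm genes, 6 fell and 1 rose, with a median of -0.49; adjusted over the list alone, 10 fell and 1 rose. The adaptor Nck2, the polarity kinase Prkci and the scaffold Magi2 had log2 fold changes of -0.66, -0.66 and -1.22 (adjusted p = 0.0162, 0.0308 and 0.0385), and the actin scaffold Iqgap1 rose by 0.52 (adjusted p = 0.0332). The list's score was lower (difference -0.37, exact permutation p = 0.0159, adjusted p = 0.0456; camera adjusted p = 0.000538, and adjusted p = 0.484 with an estimated correlation). The paired fit called 12 lower and 1 higher. Without Cosmc KO 1 the counts were 15 lower and 3 higher, and leaving out any 1 of the other 8 libraries left 0 to 2 lower. With the tubule score as a covariate the median was -0.24, with 1 higher and 0 lower. Magi2 was no longer called when any 1 library other than Cosmc KO 1 was left out (adjusted p = 0.062 to 0.116). Prkci was not called when any 1 of controls 1, 2, 4 and 5 or Cosmc KO 2, 3 and 4 was left out (adjusted p = 0.0565 to 0.0979). Nck2 was not called when any 1 of Cosmc KO 2 and 3 was left out (adjusted p = 0.0502 to 0.0542). Iqgap1 was not called when any 1 of controls 2, 3, 4 and 5 or Cosmc KO 3 and 4 was left out (adjusted p = 0.0694 to 0.0819).

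The other glomerular cell types did not follow the podocyte list. Of 32 endothelial genes 2 rose, Eng (endoglin, 0.86 ± 0.13, adjusted p = 0.00539) and Egfl7 (0.52 ± 0.11, adjusted p = 0.0226), none fell, and the median was 0.02 (camera adjusted p = 0.674). Egfl7 was not called when any 1 of controls 1 and 4 or Cosmc KO 2 and 4 was left out (adjusted p = 0.0504 to 0.0623). Without Cosmc KO 1, 3 endothelial genes rose and 6 fell, and 1 rose without control 1, control 4, Cosmc KO 2 or Cosmc KO 4. Of 28 mesangial and vascular muscle genes 5 rose and 2 fell, with a median of 0.07 (camera adjusted p = 0.300). Tagln, Serpine2, Myl9 and Mcam rose by 1.09, 0.81, 0.62 and 0.57. Leaving out Cosmc KO 1, 4 mesangial genes fell, and leaving out any 1 of the other 8 libraries left 0 or 1 lower. Without control 1 camera called the mesangial list (adjusted p = 0.0465, and adjusted p = 0.616 with an estimated correlation). The paired fit gave 3 higher and 4 lower endothelial genes, and 6 higher and 5 lower mesangial genes. Adjusted over each list alone, 2 endothelial genes rose, and 6 mesangial genes rose and 4 fell. Of 18 parietal epithelial genes, markers of the cells lining Bowman's capsule, 4 rose and 1 fell, and 9 rose and 1 fell over the list alone. Aldh1a2, which makes retinoic acid, rose from 455 ± 82.1 to 1790 ± 415 (1.96 ± 0.18, adjusted p = 0.000357), the tight-junction gene Cldn1 rose by 1.70 and Akap12 by 0.77, while Ncam1 fell (-0.97 ± 0.17, adjusted p = 0.0105). The parietal score was higher in all 4 Cosmc KO libraries than in any control (difference 0.80, exact permutation p = 0.00794, the smallest possible, adjusted p = 0.0365; camera adjusted p = 0.000137, and adjusted p = 0.292 with an estimated correlation). The paired fit gave 12 higher and 1 lower, and without Cosmc KO 1 the counts were 13 and 2. The parietal scores of Cosmc KO 1 to 4 were 10.21, 10.92, 10.75 and 10.39, highest in the libraries with the highest proximal tubule scores, and the list median moved from 0.89 to 0.42 with the tubule score as a covariate (4 rose, 1 fell).

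Proximal tubule transcripts varied widely between libraries. All 33 measured markers had a positive log2 fold change (median 1.40), but none passed limma's test (exact permutation p of the score = 0.143; camera adjusted p = 2.92e-06, and adjusted p = 0.532 with an estimated correlation). The abundant markers Gpx3 and Slc34a1 read 82999 ± 48778 and 16730 ± 10975 in controls, against 243757 ± 176051 and 51939 ± 37230 in Cosmc KO. The scores were 9.65, 11.38, 11.38, 10.64 and 9.02 in controls 1 to 5 and 9.97, 12.69, 12.64 and 11.74 in Cosmc KO 1 to 4. Of the 33, 29 rose in the paired fit, and 26 rose without Cosmc KO 1. When Cosmc KO 1 was left out, Gpx3 and Slc34a1 passed (adjusted p = 0.0252 and 0.0234), as they did in the paired fit (adjusted p = 0.0222 and 0.0119). Of 26 distal nephron genes 1 fell, Pvalb, a marker of the distal convoluted tubule (1974 ± 976 to 449 ± 251, adjusted p = 0.0178), and the median was 0.14 (camera adjusted p = 0.682, direction down). With the proximal tubule score as a covariate the distal median was -0.79 and 4 fell (camera adjusted p = 4.97e-10, and adjusted p = 0.28 with an estimated correlation). The paired fit called 1 higher and 4 lower. Leaving out Cosmc KO 1 gave 3 higher and 2 lower, Cosmc KO 3 2 lower and Cosmc KO 2 none. Pvalb was not called without Cosmc KO 2 (adjusted p = 0.0543). None of the 8 red blood cell transcripts passed limma's test, although all 8 were lower (median -1.38), 7 of them past the threshold over the list alone. Hbb-bs read 16535 ± 3337 and 8066 ± 5659, and Hba-a1 8404 ± 2542 and 4306 ± 3472; reads of these globin copies may be shared. The red cell score difference of -1.25 had an exact permutation p of 0.0159 (adjusted p = 0.0456; camera adjusted p = 0.000538, and adjusted p = 0.484 with an estimated correlation), and 5 members fell in the paired fit. The counts of red cell members that fell without Cosmc KO 1 and without Cosmc KO 4 were 6 and 4. With Cosmc KO 1 left out, Hbb-bs passed (adjusted p = 0.0336; 0.045 in the paired fit with all 4 pairs). Without Cosmc KO 4, Hba-a1 passed (adjusted p = 0.044). None of the 13 mitochondrially encoded transcripts passed (median 0.03; camera adjusted p = 0.879); mt-Co1 and mt-Cytb had log2 fold changes of 0.01 and 0.03.

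**Figure D3:**
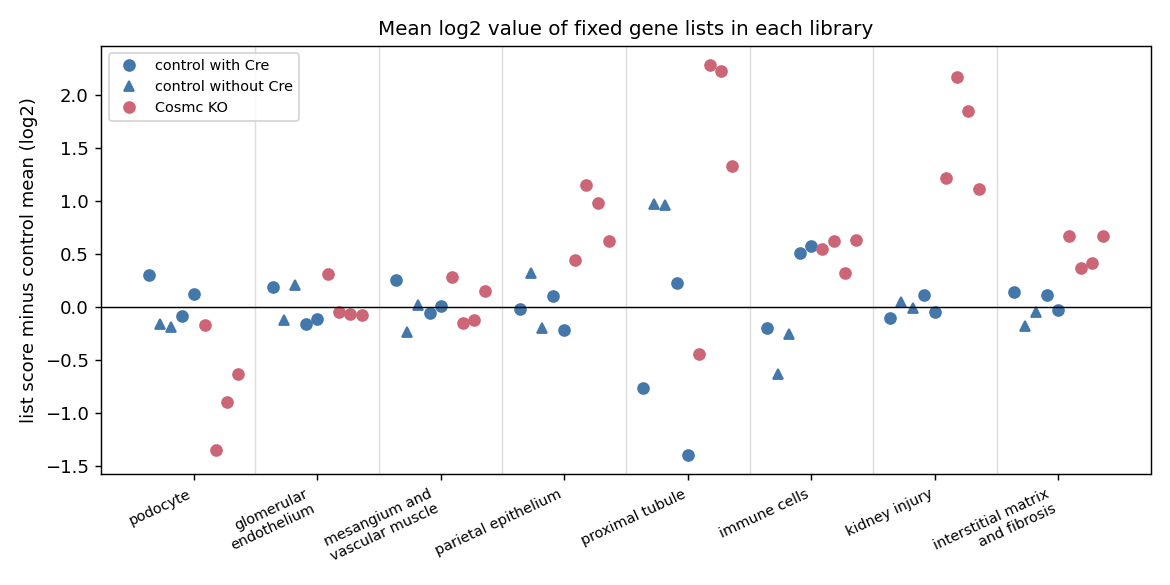
Score of 8 fixed gene lists (mean log2(value + 1) of the members) in each library, minus the control mean; blue circles are controls with Cre, blue triangles controls without Cre and red circles Cosmc KO, ordered by replicate number within each group. The kidney injury score (10.33 to 11.39 in Cosmc KO, 9.12 to 9.33 in controls) separates the groups, whereas the proximal tubule score overlaps.

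Of 37 kidney injury genes 24 rose and none fell, 29 rose over the list alone, and the median log2 fold change was 1.31. Lcn2, the iron-binding injury marker NGAL, rose from 41.9 ± 16.2 to 805 ± 677 (3.95 ± 0.53, adjusted p = 0.00278). S100a6, a calcium-binding protein, rose from 1691 ± 157 to 4464 ± 1311 (1.36 ± 0.17, adjusted p = 0.00186), and Plau (urokinase) from 4352 ± 346 to 8689 ± 1498 (0.98 ± 0.12, adjusted p = 0.00208). Timp1, an inhibitor of metalloproteinases, rose by 1.83 ± 0.24 (adjusted p = 0.00271). The score was higher in every Cosmc KO library than in any control, Cosmc KO 1 included (10.43). The difference was 1.59 (exact permutation p = 0.00794, the smallest possible, adjusted p = 0.0365; camera adjusted p = 1.35e-17, and adjusted p = 0.165 with an estimated correlation, which was 0.0319 without Cosmc KO 4). With the tubule covariate 20 members rose, and leaving out single libraries gave 17 to 29; 1 member fell without Cosmc KO 1.

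Of 25 complement and coagulation genes 5 rose and 1 fell (10 and 2 over the list alone; median 0.30). C3, the central complement component, rose from 556 ± 195 to 6221 ± 4635 (3.22 ± 0.54, adjusted p = 0.00805), and the thrombin receptor F2r rose by 0.88. The score difference was 0.61 (exact permutation p = 0.00794, adjusted p = 0.0365; camera adjusted p = 0.0168, and adjusted p = 0.36 with an estimated correlation), and the paired fit called 11 higher and 3 lower. In the absence of Cosmc KO 1, 9 rose and 4 fell and camera no longer called the list (adjusted p = 0.23), and without Cosmc KO 3, 3 rose. Camera also did not call it with the stricter filter (adjusted p = 0.0603). Of 32 immune cell genes 9 rose and none fell (11 rose and 1 fell over the list alone; median 0.53). C1qa, C1qb and C1qc, which encode the complement C1q chains, rose by 2.58, 2.38 and 2.34 (adjusted p = 0.00445, 0.00624 and 0.00344), and the macrophage receptor gene Csf1r by 1.14 (adjusted p = 0.0116). The immune score overlapped between groups (difference 0.53, exact permutation p = 0.103; camera adjusted p = 0.000554, adjusted p = 0.532 with an estimated correlation, and 0.1 with Cre-carrying controls only). The paired fit gave 19 higher and 1 lower; 4 rose without Cosmc KO 3, and 5 rose without Cosmc KO 2 or without control 3. Of 31 interferon response genes 4 rose and none fell (7 over the list alone; median 0.28): Ifi27l2a by 1.22, Oas3 by 1.08, Usp18 by 0.62 and Oas1a by 0.48. Its score difference of 0.34 had an exact permutation p of 0.0317 (adjusted p = 0.073; camera adjusted p = 1.29e-05, and adjusted p = 0.484 with an estimated correlation), and 11 rose in the paired fit. Once Cosmc KO 1 was left out, 8 interferon genes rose, while 2 rose without control 2, 4 or 5 or Cosmc KO 2, and 1 without Cosmc KO 3 or 4. Usp18 was not called when any 1 of controls 2, 3, 4 and 5 or Cosmc KO 2, 3 and 4 was left out (adjusted p = 0.055 to 0.108). Oas1a was not called when any 1 of controls 1, 2, 4 and 5 or Cosmc KO 3 and 4 was left out (adjusted p = 0.054 to 0.0915). Oas3 was not called when any 1 of Cosmc KO 2, 3 and 4 was left out (adjusted p = 0.0541 to 0.0592).

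Matrix genes changed in both directions. Of 34 interstitial matrix and fibrosis genes 15 rose and 2 fell (18 and 3 over the list alone; median 0.43). Col8a1 rose from 1467 ± 453 to 9028 ± 790 (2.67 ± 0.20, adjusted p = 0.000159), Tnc (tenascin C) from 1034 ± 341 to 6227 ± 813 (2.65 ± 0.24, adjusted p = 0.000357), Col3a1 by 1.58 and Col5a1 by 1.52. The score difference was 0.53 (exact permutation p = 0.00794, adjusted p = 0.0365; camera adjusted p = 9.47e-07, and adjusted p = 0.425 with an estimated correlation). After leaving out Cosmc KO 1, 4 matrix genes fell, and leaving out any 1 of the other libraries left 1. Of 23 glomerular basement membrane genes 8 rose and none fell (8 and 3 over the list alone), and the median was -0.01, while the mean and camera (adjusted p = 0.165) pointed upward. The collagen IV chains Col4a1 and Col4a2 rose by 1.12 ± 0.15 and 1.06 ± 0.13 (82355 ± 9735 to 178438 ± 15080 for Col4a1, adjusted p = 0.00286), and the nidogens Nid1 and Nid2 by 0.98 and 0.82. The annotated exons of Col4a1 and Col4a2 overlap, so reads may be shared. In the paired fit 4 members of this list fell besides the 8 that rose, the same counts as without Cosmc KO 1, and 5 rose without Cosmc KO 2 or without Cosmc KO 3. Camera called the basement membrane list without control 1 (adjusted p = 0.0465, and adjusted p = 0.591 with an estimated correlation) and without Cosmc KO 2 (adjusted p = 0.0222, and adjusted p = 0.553 with an estimated correlation). Of 40 actin regulators 10 rose and 1 fell (17 and 2 over the list alone; median 0.18), led by Myh10 (0.94 ± 0.12), Capg (0.91 ± 0.12), Zyx (0.82 ± 0.13) and Tpm1 (0.60 ± 0.10). Their score difference of 0.21 had an exact permutation p of 0.0238 (adjusted p = 0.0608; camera adjusted p = 6.17e-05, and adjusted p = 0.484 with an estimated correlation), and the paired fit gave 13 higher and 3 lower. Excluding Cosmc KO 1, 2 fell, and no actin regulator fell when any 1 of the other libraries was left out.

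Of 26 measured enzymes of mucin-type O-glycosylation 1 rose and 2 fell (2 and 6 over the list alone; median 0.13, camera adjusted p = 0.434). Besides C1galt1c1, the sialyltransferase St6galnac6 fell (-0.73 ± 0.18, adjusted p = 0.0382), and Galnt2, which starts O-glycan chains, rose by 0.50 ± 0.13 (adjusted p = 0.0435; 0.0501 in the paired fit). St6galnac6 and Galnt2 were each no longer called when any 1 library other than Cosmc KO 1 was left out (adjusted p = 0.0589 to 0.116 and 0.0543 to 0.13). Both calls were also lost with the tubule score as a covariate (-0.42 and 0.44, adjusted p = 0.0907 and 0.16). The paired fit called 5 higher and 5 lower, and the counts were 9 and 6 without Cosmc KO 1. Leaving out any 1 of the other 8 libraries left 0 higher and 1 lower. Of 26 mucin-like glycoproteins, proteins that carry dense O-glycans, 3 rose and none fell (4 and 1 over the list alone; median 0.04, camera adjusted p = 0.300): Havcr1, Mcam and Lrp1 (0.53 ± 0.13, adjusted p = 0.0358). The mean change and score difference was 0.38, with Havcr1 at 5.74, and the score had an exact permutation p of 0.00794 (adjusted p = 0.0365; camera adjusted p = 0.532 with an estimated correlation). Lrp1 was not called when any 1 of controls 2, 3, 4 and 5 or Cosmc KO 2, 3 and 4 was left out (adjusted p = 0.0532 to 0.0852). In the paired fit 7 rose and 2 fell, and without Cosmc KO 1 the counts were 7 and 4.

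Of 31 immediate early genes 5 rose and none fell (6 over the list alone; median 0.28), among them Cyr61 (1.14 ± 0.13), Gadd45b (1.22 ± 0.17), Myc (1.58 ± 0.26) and Egr2 (1.28 ± 0.24). The score had an exact permutation p of 0.0635 (camera adjusted p = 0.00014, and adjusted p = 0.484 with an estimated correlation), and 11 rose and 2 fell in the paired fit. Of 30 unfolded protein response genes 2 rose, Asns (0.65 ± 0.14) and Sesn2 (0.99 ± 0.24), and none fell (also 2 over the list alone; median 0.06, camera adjusted p = 0.414); the paired fit called 4 higher and 1 lower. Sesn2 was no longer called when any 1 library other than Cosmc KO 1 was left out (adjusted p = 0.058 to 0.112). With the tubule score as a covariate neither Sesn2 (0.57, adjusted p = 0.0673) nor Asns (0.50, adjusted p = 0.105) was called. Asns was not called when any 1 of controls 1, 3 and 5 or Cosmc KO 2 and 3 was left out (adjusted p = 0.054 to 0.0896). When Cosmc KO 1 was excluded, 2 unfolded protein response genes also fell, and without Cosmc KO 4 camera called the list (adjusted p = 0.0113, and adjusted p = 0.652 with an estimated correlation). None of 30 cell cycle genes passed limma's test, over all genes or over the list alone, although 29 had positive fold changes (median 0.62, exact permutation p of the score = 0.0397, adjusted p = 0.083; camera adjusted p = 2.92e-06, and adjusted p = 0.532 with an estimated correlation). Mki67 read 1672 ± 644 and 2407 ± 471, and Pcna 3349 ± 305 and 3639 ± 124. The cell cycle median was 0.40 with the tubule score as a covariate. In the paired fit 15 cell cycle genes rose, and 5 rose without Cosmc KO 1. Of 25 cholesterol synthesis genes only Dhcr7 was called (-0.75 ± 0.11, adjusted p = 0.00461), also over the list alone, and the median was -0.05 (camera adjusted p = 0.491); 2 rose and 1 fell in the paired fit. Of 27 fatty acid oxidation and PPAR genes Plin2 rose (0.61 ± 0.14, adjusted p = 0.0321) and the fatty acid transporter gene Cd36 fell (-1.01 ± 0.18, adjusted p = 0.0103), the same counts over the list alone, with a median of 0.13 (camera adjusted p = 0.179); 4 rose and 1 fell in the paired fit. Plin2 was not called when any 1 of controls 1, 2 and 4 or Cosmc KO 2, 3 and 4 was left out (adjusted p = 0.0537 to 0.101). With Cosmc KO 1 excluded, 8 fatty acid genes rose, as did 5 cholesterol genes, while 2 cholesterol genes fell, and camera called the fatty acid list (adjusted p = 0.0177, and adjusted p = 0.717 with an estimated correlation).

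Across the 23 lists, camera called 13 at the preset correlation and 0 with an estimated correlation (1 without Cosmc KO 4), fry called 5, and the exact permutation test of scores called 8. With the estimated correlation 0 lists were also called in the paired fit. With the proximal tubule score as a covariate, camera called 18 lists at the preset correlation, 12 of them among the 13, and 0 with an estimated correlation. The proximal tubule list was no longer called (adjusted p = 0.538), which was fixed in advance because the covariate is the score of this same list. The 6 lists gained were mesangium and vascular muscle (adjusted p = 0.00288, up), glomerular basement membrane (0.00038, up), mucin-like glycoproteins (0.0333, up), distal nephron, cholesterol synthesis (0.00214, down) and mitochondrially encoded transcripts (0.000879, down). Their adjusted p with an estimated correlation ranged from 0.272 to 0.415.

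The controls pooled animals with and without Cre, and a second comparison asked how far these differed. Prm1, which encodes the sperm nuclear protein protamine 1, was the only gene called by limma among 16764 (log2 fold change 9.21 ± 0.39, adjusted p = 0.00281). It read 3283, 1892 and 2851 in the Cre-carrying controls 1, 4 and 5, and 5.47 and 2.00 in controls 2 and 3. The Cosmc KO libraries, all with Cre, read 1078, 424, 683 and 711. Prm1 lies on chromosome 16, from 10796326 to 10805839. An unadjusted p under 0.05 was found for 1356 genes; edgeR on the recovered reads also called 1 gene, and DESeq2 called 333, 9.91% of them higher with Cre. Leaving out control 1 ended the Prm1 call (adjusted p = 0.0529; 0 genes called), and leaving out control 4 raised the count to 176. The proximal tubule scores of the Cre-free controls (11.38 and 11.38) lay above those of the Cre-carrying controls (9.65, 10.64 and 9.02).

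**Figure D4:**
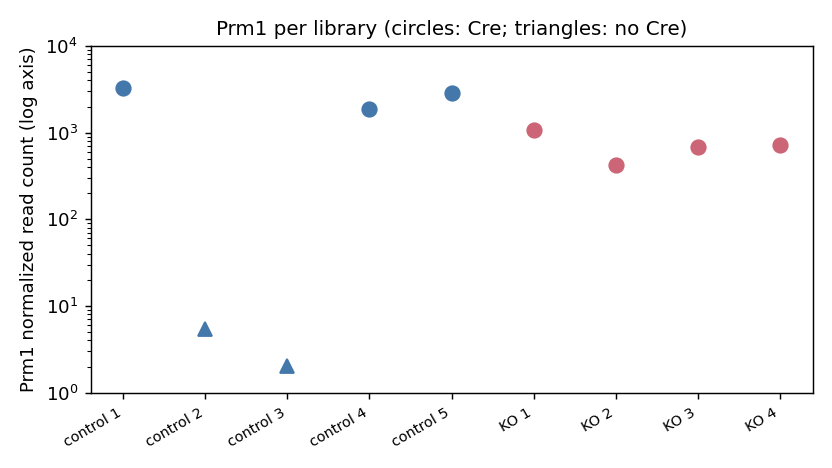
Normalized read count of Prm1 in each library on a log axis, with controls in blue and Cosmc KO in red; circles mark animals with Cre and triangles animals without. The 7 libraries with Cre read 424 or more, and the 2 without read 5.47 and 2.00.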

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

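The tests below of tubule dilution, of equal podocyte loss and of the tubule covariate were chosen after the results were seen; those of other splits and of the immune covariate were set beforehand.

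Among 244 groups of values examined, 13 held a library far from the rest of its group, where chance alone gives about 12.2. Control 1 held the single control read of Crct1 and that of Mmp10 (1.06 each, the others at 0). Control 2 held all control reads of Il1f6 (6.83, the others at 0) and the lowest control value of Mcam (9839 against 11510 to 11987). Sprr1a was 13.7 in control 4 against 1.37 to 2.16 in the other controls. Plau was 3759 in control 5 against 4353 to 4612, and C3 was 222 in control 3 against 586 to 718. Control 1 had the highest Shisa3 (44521 against 27500 to 30277) and slit diaphragm score (12.84 against 12.56 to 12.64). In the Cosmc KO group, Gpr165 was 187 in Cosmc KO 4 against 65.5 to 76.4. Cosmc KO 1 held the lowest Lect1 (12.3 against 15.2 to 15.3), the highest Tnc (7438 against 5687 to 5892) and the highest endothelial score (14.0 against 13.6 in the others).

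The 1298 genes called between Cosmc KO and control were set against other splits of the 9 libraries into 4 and 5. Of 100 splits drawn from the 126 possible, 1, the real split, called as many genes. This share is under 0.05, but only over splits that ignore the pairs. The highest other split called 463. The same held for the 698 higher genes (1 split; highest other 12) and the 600 lower genes (1 split; highest other 451). That highest split grouped controls 1, 4 and 5 with Cosmc KO 1, the 4 libraries with the lowest proximal tubule scores. Among the 10 drawn splits that part all 4 numbered pairs, the other 9 called 0 genes, but these splits are too few for a share under 0.05, and among the 90 that part fewer pairs the median was 0. For the 13 lists called by camera at the preset correlation, chance cannot be excluded: 40 splits called as many, and the highest other called 18.

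The lower podocyte list is the first pattern to follow up. Tubule RNA diluting the glomerular RNA was predicted to lower endothelial and podocyte transcripts alike. The podocyte score fell against the endothelial score by 0.79 (exact permutation p = 0.0159). Controls 2 and 3 had the highest control tubule scores. Their podocyte scores (14.29 and 14.27) were also below those of controls 1, 4 and 5 (14.37 to 14.75). Their endothelial scores were not lower (13.58 and 13.90, against 13.53 to 13.89), so this comparison cannot decide. Against the mesangial score the podocyte score fell by 0.80 (exact permutation p = 0.00794, the smallest possible). That would go against dilution only if the mesangial and vascular transcripts came from the glomeruli alone, which was not tested. Control 3, with a higher tubule score, also had a mesangial score (12.623) no lower than those of controls 4 and 5 (12.548 and 12.616). In addition, 5 members of the mesangial list rose in Cosmc KO. The mesangial comparison therefore cannot decide either. An equal loss of every podocyte transcript was predicted to leave none of the other 37 members below the mean of the 6 fixed podocyte genes. However, 4 were below it, Shisa3 and Thsd7a among them (-1.22 and -1.07 relative to that mean, adjusted p = 0.00602 and 0.00939), and 6 were above it. The list members thus changed by unequal amounts. As other cells of the preparation may also hold some of these transcripts, an equal loss from podocytes could do the same, so this test cannot decide. Neither dilution as the whole cause nor an equal loss is thus decided. The median of the podocyte list moved from -0.80 to -0.42 with the tubule covariate. Fewer podocytes together with unequal changes in those that remain was not tested and stays open.

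The higher kidney injury list is the second. If tubule RNA carried over with the glomeruli accounted for it, the list's median of 1.31 would drop below 0.5 of its value with the proximal tubule score as a covariate, but it was 1.04 with 20 of 37 members still called higher (camera adjusted p = 1.18e-21, and adjusted p = 0.145 with an estimated correlation). With the immune score as a covariate, more immune cells in the glomeruli would do the same, but the median was 1.42 with 11 members called higher (camera adjusted p = 1.77e-16, and adjusted p = 0.306 with an estimated correlation). Tubule RNA as the whole cause, as far as it follows its score, is argued against by the median and the members called. For immune cells only the median goes against it, as the members called went from 24 to 11. The list's camera calls do not add to either, as they need the preset correlation. The immune score overlapped between the groups, whereas C1qa, C1qb, C1qc and Csf1r did not. An increase of the cells that carry these genes is therefore not decided by this covariate. Carried-over tubule RNA low in the listed markers would escape the covariate and stays open. Havcr1 (2490 and 1439) and Lcn2 (1753 and 829) were highest in Cosmc KO 2 and 3, the libraries with the highest proximal tubule scores. In Cosmc KO 1 and 4, Havcr1 read 267 and 214 and Lcn2 290 and 346. Which cells carry these transcripts stays open, as the libraries pool all cell types of the preparation.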

How the results depend on the processing

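edgeR, TMM factors alone, the pseudocounts, leaving out Cosmc KO 2 and 3 together or a Cre-free control, and estimated correlations in the paired, tubule-covariate and other alternative fits were tests chosen after the data were seen. The direction of C1galt1c1 held under all 25 alternatives (log2 fold change -0.71 to -0.51). Of the 84 named genes called, 44 kept their call under every alternative that tested them, except a fold threshold. The stricter filter tested only 78 of the 84, and a gene it removed was not counted as lost. The counts of genes called (1298; 698 higher, 600 lower) were 2699 (1447 and 1252) with DESeq2, 3652 (1990 and 1662) with age as a factor, 438 (284 and 154) with Cre-carrying controls only, 730 (459 and 271) with the proximal tubule score as a covariate, 305 (224 and 81) without Cosmc KO 2 and 3 together and 540 (333 and 207) at an absolute log2 fold change of at least 1. The share called higher, 53.8%, was 44.1% with TMM factors alone (677 higher, 857 lower), 48.8% with upper-quartile factors (628 and 659) and 43.3% with limma-voom and TMM (718 and 942). Leaving out single libraries gave 523 to 4884 (348 to 2439 higher, 175 to 2445 lower). With the replicate number as a block the paired fit gave 2790 (1601 and 1189) and changed the call of no gene or list named in the results other than those given there. The age factor groups the libraries as this block does, with control 5 joined to number 4, so it is not a separate check. C1galt1c1 was -0.61 with Cre-carrying controls only and -0.67 without Cosmc KO 2 and 3 (not called), and -0.63 is under the fold threshold of 1. Against Cre-carrying controls only, Prm1 was lower in Cosmc KO (-1.92, adjusted p = 0.023). Of the 23 lists, 13 were called by camera, 18 with the tubule covariate (12 of the 13), 20 without Cosmc KO 2 and 3, 5 by fry and 0 with an estimated correlation (also 0 with the replicate block or the tubule covariate; 1, kidney injury, without Cosmc KO 4 or without Cosmc KO 2 and 3). Complement and coagulation was not called with the stricter filter (12 called, adjusted p = 0.0603) or without Cosmc KO 1 (adjusted p = 0.23; 13 called, 12 of the 13). Against Cre-carrying controls only, also 13 with 12 shared, the immune list was not called (adjusted p = 0.1) and the fatty acid list was (adjusted p = 0.0169, and adjusted p = 0.607 with an estimated correlation). The mitochondrially encoded list was lower with the tubule covariate (median -0.48, adjusted p = 0.000879) and without Cosmc KO 2 and 3 (-0.45, adjusted p = 0.00382). Between Cre-carrying and Cre-free controls, DESeq2 called 333 genes and leaving out each of the 5 controls gave 0 to 176, against 1; without control 2 or 3, the lone Cre-free library is assumed to vary like the others.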

Other observations

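The test of the Cre transgene below was chosen after the values were seen; that of germ cell genes was set before its result was seen. The genes in the next paragraph were chosen after their values were seen.

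Further single genes rose in Cosmc KO; no test of them as groups was made. Of the fibrinogen chain genes, Fga rose from 22.1 ± 13.8 to 654 ± 504 (log2 fold change 4.60 ± 0.64, limma adjusted p = 0.00306), Fgb by 2.87 ± 0.51 and Fgg by 4.70 ± 0.59. Gpnmb and Mmp12, genes known from activated macrophages, rose by 3.97 ± 0.44 and 3.03 ± 0.35 (adjusted p = 0.00108 and 0.00145). Anxa8 rose by 4.56 ± 0.55 and Il1rn, the interleukin-1 receptor antagonist, by 2.89 ± 0.57. Each of these was higher in all 4 Cosmc KO libraries than in any control.

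Among the collagen IV chains, chosen after their values were seen, Col4a1 and Col4a2 rose. Col4a3, Col4a4 and Col4a5, the chains of the mature glomerular basement membrane made by podocytes, did not pass, with log2 fold changes of -0.95, -0.81 and -0.68 (limma adjusted p = 0.0761, 0.065 and 0.0956). In the paired fit these 3 passed (adjusted p = 0.013, 0.00843 and 0.0227). The difference between the chains was not tested.

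Prm1 is the third pattern to follow up. All 7 libraries with Cre exceeded both without (exact permutation p = 0.0278, the smallest possible over 36 splits), but Prm1 was picked because it separated controls with and without Cre, so this p decides nothing. Whether it comes from sequence carried by the Cre transgene stays open. RNA from testis or sperm would bring other male germ cell genes, but of 6 listed genes from a panel of 17, 0 had every Cre library above both others. All 6 were also read without Cre, up to 19.0 (Gapdhs) to 1831 (Odf2), so they can tell little. Panel genes such as Prm2 and Tnp1 are not among the listed genes, whose lowest mean is 8.73. The transgene's sequence was not analysed here.

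Capn11 followed the replicate numbers and not the groups. It read 28.6, 55.7 and 104 in controls 1, 4 and 5 and 67.4 and 59.9 in Cosmc KO 1 and 4, but 1.37 and 0 in controls 2 and 3 and 0.897 and 0.764 in Cosmc KO 2 and 3. It was singled out after its values were seen.

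Genes near Cosmc on chromosome X were not called more often than others. Of 43 tested genes within 10 Mb of C1galt1c1, 1 was called (2.33%), against 7.86% of 16216 genes elsewhere (Fisher's exact test, two-sided p = 0.256).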
